A study of Mus musculus with 26 samples.

How the data were processed

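The study set T cell acute lymphoblastic leukaemia (T-ALL) samples of mice against sorted stages of T cell development, with total RNA measured on Illumina bead arrays in 26 samples. Per the labels' protocols, all work was done in vivo, samples were either sorted or taken straight from cell suspensions (which samples were sorted is not said), RNA was isolated with RNAzol B, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. The scanner software, bead summary and background treatment are not given in the sources used here.

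The deposited signal intensity of each probe on each array was not normalized and not background subtracted, per the file headers and the lowest values. The thymocyte table held 46237 probes and the table for T-ALL held 46089, all of which were in the thymocyte table as well. The deposited detection p-value of each probe was one-sided in the thymocyte table and two-sided in the T-ALL table, as the values show, and the T-ALL p-values were turned into one-sided ones with the median signal of probes with p above 0.9 as the background level. One more deposited table held log2 values whose columns shared the same sorted values to within 0.01, with a median of 6.79 in every column, a minimum of 6.31 and a maximum of 14.97. Each T-ALL column of that table ranked its probes as the array's own signals did by probe ID (Spearman's rho across probes, 0.999919 for each column). The thymocyte columns matched their signals by position in the table of T-ALL probes (rho across probes from 0.999918 to 0.999919) and not by probe ID (from -0.00304 to 0.00657). That table was therefore used only as an alternative, once by probe ID as planned and once with 45941 lines realigned, which was chosen after seeing the data. Its scale is log2 of signal with no centring and all columns run in the same direction, while how its authors reached it is not stated.

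Signals were background corrected with the detection p-values, given an offset of 16 and quantile normalized (the neqc method in limma 3.58.1, R 4.3.3, the data.table package, version 1.17.8). The thymocyte arrays and the T-ALL arrays were each normalized by themselves for comparisons within them, and all 26 arrays together for T-ALL against the stages. A probe was kept where its detection p was under 0.05 on at least 2 arrays of the fit. Of the probes common to both tables, 35667 had 1 gene symbol in the platform annotation, 0 had several and 10422 had none. Symbols were updated through the Entrez ID for 28519 probes and through the accession for 2634, and kept from the platform annotation for 4514, which changed 937 symbols. These probes name 21903 genes, of which 8483 have several probes. Each gene was represented by the probe with the highest mean over all 26 arrays. The genes tested came to 15881 among the stages, 15032 among the T-ALL arrays and 17417 over all arrays. Over the other probes of called genes, the share with the direction of the chosen probe was 81.0% from ETP to TN2, 79.0% from TN2 to TN3a, 90.6% from TN3a to TN3b and 84.5% from ISP to DP. The share was 77.8% for the T-ALL groups against each other, 71.5% for Rag-proficient and 72.0% for Rag-deficient T-ALL against the stages.

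Groups were taken from the labels. Comparisons were fitted with limma (lmFit, then eBayes with an intensity trend) and called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The 16 thymocyte arrays entered one fit with a moderated F test over the 7 stages and a contrast for each step, since most stages have only 2 arrays. The 10 T-ALL arrays entered a fit of their own, and all 26 arrays entered one more fit in which each T-ALL group was set against the equally weighted mean of the stage means and, for Rag-proficient T-ALL, against each stage (called and at least 2-fold in each of the 7 contrasts). The design, the tests, the gene lists, the rule for named genes and the alternatives not marked otherwise were fixed before the data were examined. The rule named, for each comparison, the 5 called genes with the largest rise and the 5 with the largest fall whose group values did not overlap, up to 2 called members of each list in each direction, Rag1, Rag2 and the sort markers, and any human T-ALL oncogene with an outlying T-ALL array.

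Where a probe was not above background on any array of a group, the difference is given as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own. Such folds are means of normalized log2 values. Other changes are log2 differences with their standard error (SE).

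The 26 gene lists were: progenitor genes, T-lineage commitment and pre-TCR signalling, Notch target genes, beta-selection response, double-positive stage genes, proliferation genes, MYC targets and ribosome biogenesis, human T-ALL transcription factor oncogenes, T-ALL tumour suppressor genes, p53 target genes, BCL2 family, glycolysis, oxidative phosphorylation, interferon response, antigen presentation, migration and adhesion receptors, cytokine receptors and signalling, mature T cell markers, innate lymphocyte markers (innate, NK and gamma delta), B cell markers, myeloid and dendritic cell markers, erythroid markers, thymic stroma markers, dissociation and stress response, sex-linked genes, and sort markers. They were tested with camera against all other genes tested, with a preset correlation of 0.01 and again with the correlation estimated from the arrays, each adjusted over the lists of a comparison, and fry was run as an alternative. Members were also adjusted over the list alone. Some genes belong to several lists, so calls of such lists are not independent. Sets of genes higher at 1 stage than at each of the other 6 were found on the thymocyte arrays only and tested in the T-ALL arrays. Stage similarity is Pearson's r across genes between a T-ALL array and a stage mean, both centred on the mean of the stage means. Similarity of the T-ALL groups was compared with an exact two-sided permutation test over all 120 splits of 10 arrays into 7 and 3, whose smallest p is 0.00833.

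The code was tested on simulated data with 200 changed genes on the arrays of each comparison. For a change of 2 on the log2 scale, 68.2% were recovered from ETP to TN2, 74.2% from TN2 to TN3a, 68.2% from TN3a to TN3b, 75.8% from TN3b to TN4, 69.7% from TN4 to ISP and 54.5% from ISP to DP. For a change of 1, the shares were 2.99%, 22.4%, 14.9%, 13.4%, 23.9% and 8.96% in the same order. The T-ALL groups against each other gave 74.2% for a change of 2 and 31.3% for a change of 1, Rag-proficient T-ALL against the stages 93.9% and 85.1%, and Rag-deficient T-ALL against the stages 92.4% and 50.7%. In these simulations small changes were thus mostly out of reach within the stages and between the T-ALL groups. The simulations changed few genes and gave a gene the same spread on every array. Shares recovered in the real data can therefore differ, above all where many genes change or an array is dim. The number of arrays limits the precision of every value.

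Arrays lay on 7 slides, 3 with T-ALL and 4 with thymocytes. Slide lot and cell kind thus cannot be told apart in any comparison of T-ALL with the stages. Strain differs along with them for Rag-proficient T-ALL, but not for Rag-deficient T-ALL. Rag-proficient T-ALL lay on slides 1, 2 and 3, and all 3 Rag-deficient arrays lay on slide 3 with 1 Rag-proficient array. The slide was used as a fixed block and as a random block. Other alternatives were no background correction, no filter on detection, detection on all arrays of a group, a 2-fold minimum, array weights, every probe, all arrays in one model, other ways of computing similarity, and leaving out each array in turn. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. For ETP, TN2, ISP and DP the arrays of a stage differed in the sex-linked genes Xist and Eif2s3y, which argues against a shared animal there. Control probes were not used here, and 148 probes of the thymocyte table alone entered no comparison.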

Results

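Gene expression was measured on 26 arrays of mouse RNA to set T-ALL, a leukaemia of T cell precursors, against the stages that thymocytes pass through. The 16 thymocyte arrays came from C57BL/6 mice and covered 7 stages: early thymic progenitors (ETP, 2 arrays), triple negative 2 (TN2, 2 arrays), TN3a (3 arrays), TN3b (2 arrays), TN4 (3 arrays), immature single positive (ISP, 2 arrays) and double positive (DP, 2 arrays). Per the labels, ETP carry CD44 and Kit, TN2 carry CD44 and CD25, TN3a and TN3b carry CD25 and are parted by CD28, TN4 carry CD28 without CD25, ISP carry CD8 without CD4, and DP carry both. The T-ALL arrays held 7 Rag-proficient samples of an F1 cross and 3 Rag-deficient samples of C57BL/6 background, so that Rag status and strain differed together. Rag stands for the recombinase of Rag1 and Rag2, which cuts antigen receptor loci for rearrangement.

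Between 41.4% and 51.3% of probes were above background on 25 of the arrays, whereas TN2 replicate 2 reached 28.5%, with a 95th percentile signal of 142 intensity units. Arrays of the same group correlated with a mean r (across probes) of 0.960 to 0.977 outside TN2 and of 0.881 between the TN2 arrays. No pair of arrays held identical values. Among the 15881 genes tested, 3683 differed between the 7 stages by limma's moderated F test, and 6802 did so without TN2 replicate 1.

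The sort markers gave a check of the labels. Kit, the stem cell factor receptor, had a mean log2 level of 12.37 in ETP (n = 2) and 5.85 in DP (n = 2), and Cd44, an adhesion receptor, 10.91 in ETP and 8.44 in TN2. Il2ra, which encodes CD25, was at 4.96 in ETP, 10.52 in TN2, 10.85 in TN3a, 8.95 in TN3b and 5.12 in TN4, and was not above background in ISP. Cd28 was at 4.53 in ETP, 7.07 in TN3a, 8.56 in TN3b, 9.08 in TN4 and 9.32 in DP, and Cd4 at 5.68 in ISP and 8.57 in DP. The Cd8a probe was above background on both DP arrays (mean 5.40) but on no ISP array, and the Cd8b1 probe was highest in ETP (12.57) and lowest in DP (10.33), so neither probe followed the CD8 sort of ISP. Rag1 was at 5.90 in ETP, 11.56 in TN3a, 9.32 in TN3b and 13.20 in DP, and Rag2 at 6.83 in TN3a and 8.38 in DP.

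**Figure D1:**
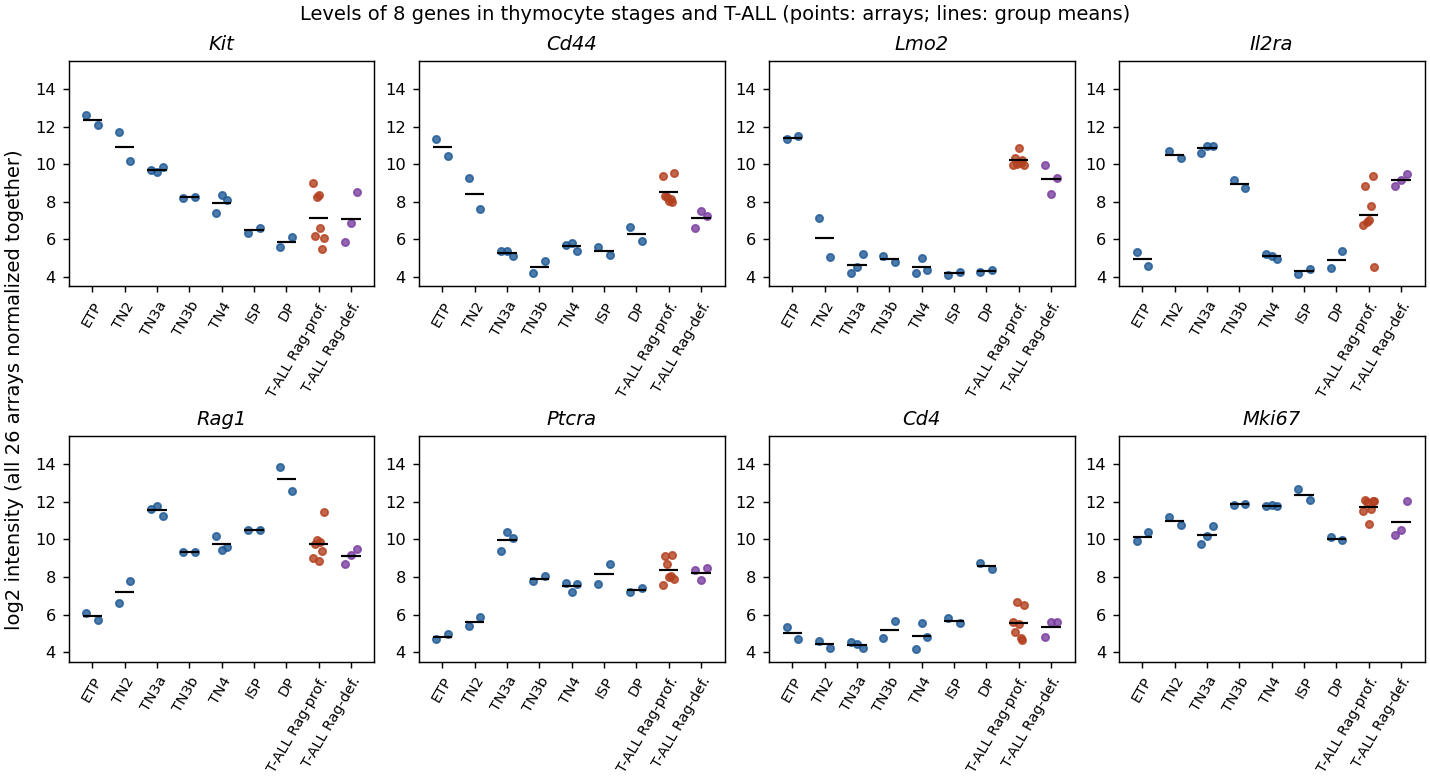
The y axis is the log2 intensity of 8 genes with all 26 arrays normalized together, the x axis gives the 7 thymocyte stages and the 2 T-ALL groups, points are arrays and lines are group means. Lmo2 falls from 11.43 in ETP and is at 10.22 in Rag-proficient and 9.22 in Rag-deficient T-ALL, while Rag1 is highest in DP at 13.20.

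The step from ETP to TN2, at which early progenitors gain CD25, was marked by the onset of T-lineage genes and the loss of progenitor genes. Cd3g and Cd3e, which encode chains of the T cell receptor complex, rose by 6.77 ± 0.25 and 5.25 ± 0.33 (log2, SE, n = 2 and 2). Bcl11b, a transcription factor needed for T cell commitment, rose by 6.47 ± 0.28, Il2ra by 5.38 ± 0.36 and Il7r, the interleukin-7 receptor chain, by 2.81 ± 0.31. Lmo2, a transcriptional regulator of blood progenitors, fell by 5.29 ± 0.50, the homeobox gene Meis1 fell by 3.93 ± 0.26, and the stem cell antigen gene Cd34 fell by 4.12 ± 0.58. With limma, 402 genes were called (145 higher and 257 lower in TN2), with adjusted p = 8.13e-10 for Cd3g and 1.29e-05 for Lmo2.

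Of 20 measured genes of T-lineage commitment and pre-TCR signalling, 7 rose, 1 fell (Cd7, by 2.06 ± 0.31) and 12 were not called, and 9 rose and 1 fell adjusted over the list alone. Of 22 progenitor genes, 11 fell and none rose, 16 of them falling adjusted over the list alone. The human T-ALL oncogenes had 5 of 15 members lower, Lmo2 and Meis1 among them (6 fell and 1 rose adjusted over the list alone). Lmo2, Meis1, Tal1, Lyl1, Mef2c, Hoxa9, Spi1 and Erg are in the progenitor list too, so this fall partly repeats that of the progenitor genes. Myeloid and dendritic markers moved with these groups: 6 of 16 fell, including Mpo, the myeloperoxidase gene (by 2.89 ± 0.37), and Elane, neutrophil elastase (at least 7.53-fold lower), and 10 fell adjusted over the list alone. Camera called these lists with a preset correlation and also with an estimated one (adjusted p = 0.00936, 0.0057, 0.00936 and 0.00215 in the order given). Of 27 proliferation genes 3 rose, such as Rrm2 (1.96 ± 0.33), and 8 did so adjusted over the list alone, but the call of the list was lost with adjusted p = 0.117 with an estimated correlation. Also lost with an estimated correlation were oxidative phosphorylation (adjusted p = 0.117, 0 of 21 called) and interferon response (0.373, 1 of 21 fell). So were cytokine receptors and signalling (0.346, 4 of 23 rose) and T-ALL tumour suppressor genes (0.127, where Bcl11b was the only member of 21 to rise).

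The count of called genes was 203 without ETP replicate 1, 189 without ETP replicate 2 and 3711 without TN2 replicate 1, which leaves the dim TN2 array alone. It was 106 with array weights, 661 with the slide as a random block and 605 with all arrays in one model. Called genes had the same direction on both slides that held 1 array of each stage, as calling largely requires. All 9 lists called with the preset correlation were also called with the slide as a fixed block, the progenitor list shifting by -1.41 on slide 4 and -1.96 on slide 6 and the T-lineage list by 1.46 and 1.78.

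**Figure D2:**
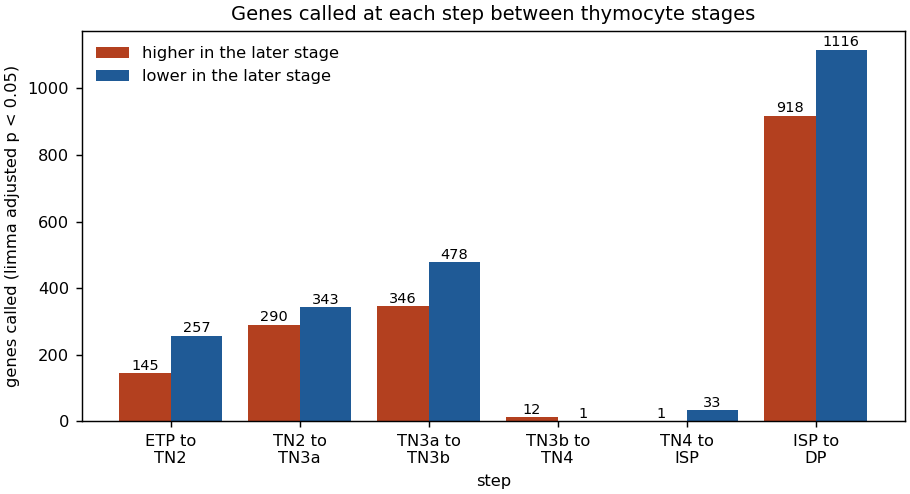
Bars show the number of genes called by limma at each step between successive thymocyte stages (x axis), higher or lower in the later stage, out of 15881 genes tested. The ISP to DP step has the most calls (918 higher, 1116 lower), and TN3b to TN4 (12 and 1) and TN4 to ISP (1 and 33) the fewest.

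From TN2 to TN3a, the step at which CD44 is lost, recombination and pre-TCR genes rose, and myeloid genes and some progenitor genes fell. Rag1 rose by 4.38 ± 0.38 (log2, SE, n = 2 and 3, limma adjusted p = 7.32e-06) and Ptcra, the pre-TCR alpha chain, by 4.25 ± 0.38. Dtx1, a target of Notch signalling, rose by 3.11 ± 0.38, Cd3e by 2.45 ± 0.30 and Hivep3, a zinc finger protein gene, by 4.73 ± 0.27. Mpo was at least 108-fold lower, the globin gene Hbb-b1 fell by 6.65 ± 0.46, and Lyl1 and Hhex, transcription factors of blood progenitors, fell by 4.57 ± 0.35 and 3.66 ± 0.47. In all 633 genes were called, 290 higher and 343 lower in TN3a.

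Of 20 T-lineage genes 10 rose and none fell (13 adjusted over the list alone), and of 17 Notch target genes 4 rose and 1 fell, Nrarp, by 1.51 (8 and 1 adjusted over the list alone). Ptcra, Cd3e and Gata3 belong to both lists, which are thus not independent. Both lists were called with an estimated correlation (adjusted p = 0.0194 and 0.018), as were the myeloid and dendritic markers (3 of 16 fell, among them Tyrobp at least 15.7-fold, 5 fell and 1 rose adjusted over the list alone, adjusted p = 0.0233). Progenitor genes (5 of 22 fell, 10 fell and 1 rose adjusted over the list alone) missed the threshold with adjusted p = 0.083 with an estimated correlation. Proliferation genes had 5 of 27 members lower, with Rrm2 down by -1.64 (11 adjusted over the list alone, adjusted p = 0.103 with an estimated correlation). Double-positive stage genes had 5 of 18 members higher, Ets2 among them (2.63, adjusted p = 0.105 with an estimated correlation), and 4 of 19 beta-selection genes rose while 1 fell (Egr1 rose by 2.87, adjusted p = 0.315 with an estimated correlation).

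Without TN2 replicate 1 the count was 4167, without TN2 replicate 2 it was 348, and it was 396 and 349 without TN3a replicates 2 and 3. The Rrm2 call ended without TN2 replicate 2 (adjusted p = 0.0911) and the Nrarp call without TN3a replicate 2 (0.0833). Array weights called 92 genes, the slide as a random block 1086 and all arrays in one model 1188. With the slide as a fixed block 987 genes were called, all 7 lists kept their call, and the Notch list shifted by 1.07 on slide 4 and 1.02 on slide 6.

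The step from TN3a to TN3b follows beta-selection, at which cells with a working TCR beta chain start to divide, and here cell cycle genes rose while Notch targets, Rag1 and cytokine signalling genes fell. Plk1 and Aurka, kinases of mitosis, rose by 2.26 ± 0.21 and 2.27 ± 0.38 (log2, SE, n = 3 and 2), and Cd2, an adhesion receptor of T cells, was at least 6.53-fold higher. Notch3 and Hes1, both Notch targets, fell by 2.68 ± 0.40 and 2.57 ± 0.31. Rag1 fell by 2.28 ± 0.38, Ptcra by 2.03 ± 0.38 and Il2ra by 1.92 ± 0.32. The largest falls also included Itgb4, an integrin chain (4.45 ± 0.41), and H19, an imprinted RNA (4.24 ± 0.42), and the cell cycle inhibitor gene Cdkn1a fell by 3.18 ± 0.44. Limma called 824 genes, 346 higher and 478 lower in TN3b, with adjusted p = 3.67e-05 for Plk1 and 2.38e-04 for Hes1.

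Of 27 proliferation genes 18 rose and none fell (23 adjusted over the list alone, camera adjusted p = 0.00584 with an estimated correlation). MYC targets and ribosome biogenesis had 5 of 23 members higher, such as Cad, an enzyme of pyrimidine synthesis (1.46 ± 0.30), and 10 adjusted over the list alone. Oxidative phosphorylation had 3 of 21 members higher, with cytochrome c (Cycs) up by 1.52 ± 0.30 (5 adjusted over the list alone). Notch targets fell in 7 of 17 cases (9 fell and 1 rose adjusted over the list alone). Interferon response genes fell in 5 of 21 cases, including Gbp2 (by 2.82 ± 0.36), and antigen presentation genes in 5 of 17. Cytokine receptors and signalling genes fell in 7 of 23 cases, led by the feedback inhibitors Socs3 (by 3.46 ± 0.32) and Cish (by 3.16 ± 0.39). Adjusted over the list alone 9, 9 and 7 of these fell. With an estimated correlation the adjusted p was 0.00549 for MYC targets, 0.0251 for oxidative phosphorylation, 0.00549 for Notch targets, 0.0406 for interferon response, 0.0241 for antigen presentation and 0.0251 for cytokine signalling. Calls were lost with an estimated correlation for the T-lineage list (2 rose and 7 fell of 20, adjusted p = 0.146) and double-positive stage genes (1 rose and 3 fell of 18, 0.268). The same was so for p53 targets (1 rose and 3 fell of 20, 0.0973) and glycolysis (3 of 16 rose, 0.256).

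The count fell to 220 without TN3b replicate 1, 259 without TN3b replicate 2 and 513 without TN3a replicate 1, and was 1296 and 1285 without TN2 replicates 1 and 2. Without TN3b replicate 1 the calls of Ptcra (adjusted p = 0.0985), Cycs (0.137) and Rag2 (0.411, -1.69 with all arrays) ended, and without TN3b replicate 2 those of Il2ra (0.0668), Aurka (0.0578) and Cad (0.111). Array weights called 2008 genes and the slide as a random block 1279. With the slide as a fixed block 1451 genes and all 11 lists were called, the proliferation list shifting by 1.44 on slide 6 and 1.28 on slide 7.

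Between TN3b and TN4, which are parted by the loss of CD25, few genes were called. Lgals3, which encodes galectin-3, was at least 24.5-fold higher in TN4, and Myo6, an unconventional myosin, was higher by 3.34 ± 0.42 (log2, SE, n = 2 and 3). Fcer1g, the common Fc receptor chain also used by innate lymphocytes, rose by 2.96 ± 0.40 and Bcl6, a transcriptional repressor, by 2.26 ± 0.33. Il2ra was the only gene to fall, by 3.68 ± 0.32 (limma adjusted p = 1.87e-04), among 13 called genes (12 higher). All arrays in one model, with another normalization, called 31 genes (23 higher and 8 lower), no background correction 6, array weights 208 and the slide as a random block 32.

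Innate lymphocyte markers shifted as a group, although only Fcer1g of 15 was called over all genes (8 rose adjusted over the list alone, camera adjusted p = 0.0311 with an estimated correlation). The same held for the beta-selection response (Egr2, an early response gene, the only 1 of 19 called, 4 adjusted over the list alone, adjusted p = 0.0311) and migration and adhesion receptors (0 of 17 called, 4 adjusted over the list alone, 0.0311). It also held for mature T cell markers (0 of 14, 4 adjusted over the list alone, 0.0477) and double-positive stage genes (Bcl6 alone of 18, 5 adjusted over the list alone, 0.0477), each with an estimated correlation. MYC targets shifted down with a mean of -0.30 and no member called (adjusted p = 0.0311 with an estimated correlation). Lost with an estimated correlation were the upward shifts of T-lineage genes (adjusted p = 0.0595), the BCL2 family (0.0595, 0 of 15 called), interferon response (0.0553) and antigen presentation (0.0595), and the downward shift of Notch targets (0.0553). At an unadjusted p under 0.05, limma gave 599 genes, fewer than the 1 in 20 of the genes tested that chance gives. Such a count does not show an absence of change, and why it lies under that share was not tested.

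The count was 121 without TN4 replicate 1, 25 without TN2 replicate 1 or TN2 replicate 2, and 8 without ISP replicate 1, ISP replicate 2, TN3a replicate 2 or TN3a replicate 3. It was 5 without TN4 replicate 2 and 2 without TN3b replicate 1, TN3b replicate 2 or TN4 replicate 3. Without TN3b replicate 1 the calls of Myo6 (adjusted p = 0.229), Fcer1g (0.238), Bcl6 (0.229) and Egr2 (0.820) ended. All 11 lists kept their call with the slide as a fixed block and the innate list shifted by 1.48 on slide 6 and 1.29 on slide 7.

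From TN4 to ISP, the CD8 single positive cells before DP, most called genes were lower, and innate lymphocyte markers fell as a group. Igfbp4, an insulin-like growth factor binding protein, was at least 24.0-fold lower, Lgals3 at least 23.5-fold lower and Fcer1g at least 9.09-fold lower in ISP (n = 3 and 2). Nkg7, a protein of cytotoxic granules, fell by 3.61 ± 0.32 (log2, SE), Myo6 fell by 4.19 ± 0.42 and Il7r fell by 2.62 ± 0.29. Limma called 34 genes, 33 lower and 1 higher (Tas2r126, a taste receptor gene, at least 2.12-fold), with adjusted p = 1.05e-04 for Nkg7. All arrays in one model called 44 genes (10 higher and 34 lower), no background correction 14 and the authors' log2 values matched by position 18, none of them higher in either, and array weights 144. At an unadjusted p under 0.05 limma gave 685 genes, again fewer than chance gives, which likewise does not show an absence of change.

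Of 15 innate lymphocyte markers 3 fell, and 10 did so adjusted over the list alone (camera adjusted p = 0.00661 with an estimated correlation). For the beta-selection response (1 of 19 fell, 7 fell and 2 rose adjusted over the list alone) the adjusted p was 0.0844 with an estimated correlation. It was 0.0585 for mature T cell markers (2 of 14 fell, 5 adjusted over the list alone) and 0.0782 for migration and adhesion receptors (2 of 17 fell). The other lists called only with the preset correlation were proliferation genes (up, 0 of 27 called, adjusted p = 0.159 with an estimated correlation), and tumour suppressor genes (up, 0.159). Lists shifting down were progenitor genes (down, 0.247), interferon response (down, 0.184), antigen presentation (down, 0.245), cytokine signalling (down, 0.183) and B cell markers (1 of 10 fell, 0.139).

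The count was 151 without TN4 replicate 1, 17 and 14 without TN4 replicates 2 and 3, and 6 and 14 without ISP replicates 1 and 2, and without ISP replicate 1 the Tas2r126 call ended (adjusted p = 0.363). With the slide as a fixed block 9 of the 11 lists kept their call, B cell markers (0.0699) and tumour suppressor genes (0.105) losing it and MYC targets gaining one (mean -0.15, adjusted p = 0.0421), and the innate list shifted by -0.96 on slide 4 and -1.76 on slide 7.

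At the step from ISP to DP, when dividing cells come to rest and rearrange the TCR alpha locus, cell cycle and biosynthesis genes fell and DP genes rose. Top2a, the topoisomerase of dividing cells, fell by 3.30 ± 0.39, and Plk1 fell by 3.21 ± 0.23 (log2, SE, n = 2 and 2). Srm, spermidine synthase, and Cad fell by 3.82 ± 0.35 and 3.56 ± 0.33, and Plac8, the largest fall, by 5.54 ± 0.23. Rag1 rose by 2.75 ± 0.42, Cd4 by 2.81 ± 0.38, Bcl6 by 3.11 ± 0.36 and St6gal1, a sialyltransferase gene, by 4.36 ± 0.78. The activation marker Cd69 rose by 4.09 ± 0.74 and Hsd11b1, a steroid dehydrogenase gene, by 5.02 ± 0.40. Limma called 2034 genes, 918 higher and 1116 lower in DP, with adjusted p = 1.67e-06 for Plk1 and 4.58e-04 for Rag1.

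Proliferation genes fell in 25 of 27 cases and MYC targets in 17 of 23 (27 and 20 adjusted over the list alone), with adjusted p = 0.00588 and 0.00055 with an estimated correlation. Double-positive stage genes rose in 10 of 18 cases and none fell (13 adjusted over the list alone, adjusted p = 0.0295 with an estimated correlation). Glycolysis genes fell in 6 of 16 cases, with triose phosphate isomerase (Tpi1) down by -2.87, and oxidative phosphorylation genes in 6 of 21, and these calls were lost with adjusted p = 0.135 and 0.0501 with an estimated correlation. Of 20 p53 targets 9 rose, such as the death receptor gene Fas (2.97 ± 0.38), and 1 fell, Gtse1, by 2.38 (adjusted p = 0.0543 with an estimated correlation). The dissociation and stress list, a sign of cell handling, had 6 of 18 members higher and 1 lower (adjusted p = 0.142 with an estimated correlation). With an estimated correlation, T-lineage genes (4 of 20 rose, adjusted p = 0.142) and beta-selection genes (6 rose and 1 fell of 19, 0.142) also lost their call. So did cytokine signalling (6 rose and 1 fell of 23, 0.273), migration receptors (2 of 17 rose, 0.272) and sort markers (2 of 9 rose, 0.272).

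Without ISP replicate 1 and ISP replicate 2 the count was 1223 and 1199. With the slide as a fixed block 10 of the 12 lists kept their call, migration receptors (0.136) and sort markers (0.0593) losing it. On slide 7, the only slide with both stages, the proliferation list shifted by -2.25 and the double-positive list by 1.57. Sex-linked genes were called as a list at no step (4 measured, 0 called, adjusted p with the preset correlation from 0.549 at TN4 to ISP to 0.938 at TN3b to TN4).

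The T-ALL groups were then set against each other, Rag-deficient minus Rag-proficient, with strain differing along with Rag. The genes lower in Rag-deficient T-ALL included some antigen receptor and stromal genes. The immunoglobulin kappa constant gene Igk-C was lower by -7.62 ± 1.26 (log2, SE, n = 3 and 7). Also lower were the T cell receptor gamma genes Tcrg and Tcrg-V4 by -4.95 ± 0.60 and -4.78 ± 0.59, and Gpx3, a plasma glutathione peroxidase gene, by -4.61 ± 0.39. Serping1, a complement inhibitor gene, differed by -4.44 ± 0.58, Sparc, a matrix protein gene, by -3.58 ± 0.57, and the chemokine gene Cxcl12 by -3.29 ± 0.44. Higher in Rag-deficient T-ALL were Aldh5a1, a dehydrogenase gene (3.36 ± 0.52), Trdv2-2, a T cell receptor delta segment (2.38 ± 0.36), and Rbm45, an RNA-binding protein gene (2.16 ± 0.23). Limma called 69 of 15032 genes, 6 higher and 63 lower, with adjusted p = 2.14e-04 for Gpx3 and 0.0165 for Igk-C. Without background correction 42 genes were called (8 higher and 34 lower), and 27 with the authors' log2 table (7 higher and 20 lower). The slide as a random block called 108 and all arrays in one model 146.

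Of 15 thymic stroma markers 2 fell, Sparc and Cxcl12, and 5 did so adjusted over the list alone. The mean shift of that list was -0.83 while its median was -0.10, and the call was lost with adjusted p = 0.161 with an estimated correlation. Erythroid markers, genes of red cells, had a mean shift of -0.57 with 0 of 10 called (adjusted p = 0.555 with an estimated correlation) and myeloid markers of -0.39 with 0 of 20 called (0.626). B cell markers had a mean of -0.81 and a median of -0.27, with 1 of 13 lower, Igk-C (0.714), and were not called with the preset correlation either. Progenitor genes shifted by -0.46 (0 of 21 called, adjusted p = 0.318 with an estimated correlation), the beta-selection response by -0.30 (0.626), oxidative phosphorylation by 0.22 (0.173) and interferon response by 0.43 (0.626), with no member called. None of the 7 lists called with the preset correlation was called with an estimated one. Rag1 and Rag2 were not called, at mean log2 levels of 9.76 ± 0.87 and 5.69 ± 1.17 (SD, n = 7) in Rag-proficient and 9.11 ± 0.41 and 5.43 ± 1.11 (SD, n = 3) in Rag-deficient T-ALL. These probes thus do not bear out the Rag label, and whether they lie in the altered part of either gene was not examined here.

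With the slide as a fixed block 24 genes were called (10 higher and 14 lower). None of the genes named here kept its call, with Gpx3 at -3.66 (adjusted p = 0.0548), Igk-C at -7.09 (0.336), Tcrg at -2.72 (0.176), Tcrg-V4 at -4.25 (0.177), Serping1 at -1.99 (0.136), and Sparc at -2.87 (0.367). Cxcl12 was at -1.93 (0.295), Aldh5a1 at 3.94 (0.120), Trdv2-2 at 2.33 (0.228) and Rbm45 at 1.82 (0.113). The blocked values rest on slide 3, which held 3 Rag-deficient arrays and 1 Rag-proficient array. On it the called genes all had the same direction. So did all 79 genes called without its Rag-proficient array, though those calls used the same Rag-deficient arrays. Within slide 3 the stroma list shifted by -0.34 (camera adjusted p = 0.658 with the block), the erythroid list by -0.09 (0.958), and the myeloid list by -1.09 (0.0205). The progenitor list shifted by -0.36 (0.292) and the beta-selection list by 0.08 (0.958). Oxidative phosphorylation (0.20) and interferon response (0.69) kept their call with the block (adjusted p = 0.0492 each). Notch targets, not called without it (mean 0.19, adjusted p = 0.754), shifted by 1.08 and were called with it (0.00281). The list values with the block are from camera with the preset correlation. The count was 35, 36 and 115 without Rag-deficient replicates 1, 2 and 3, the Igk-C and Sparc calls ended without Rag-deficient replicate 1 (adjusted p = 0.0817 and 0.0659), and the Aldh5a1 call without Rag-deficient replicate 2 (0.0765).

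**Figure D3:**
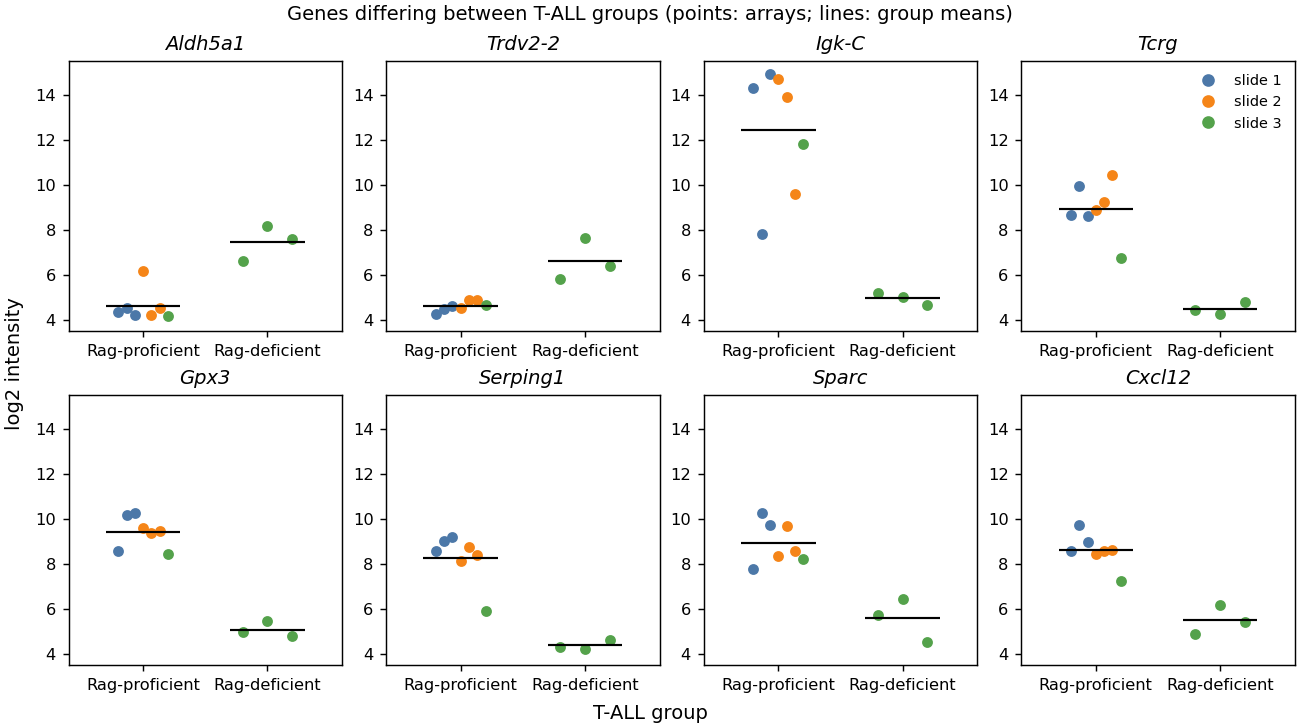
Each panel shows the log2 intensity (y axis) of a gene on the 7 Rag-proficient and 3 Rag-deficient T-ALL arrays (x axis), coloured by slide, with points for arrays and lines for group means. Igk-C ranges from 7.80 to 14.93 in Rag-proficient T-ALL and averages 4.96 in Rag-deficient T-ALL, and the slide 3 array of the Rag-proficient group has the lowest Serping1 of its group at 5.92.

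Genes specific to a stage were next followed into the T-ALL groups, which asks whether the groups labelled by Rag status differ in their place along the developmental path. The 174 genes higher in ETP than at every other stage, which include Lmo2, Tal1 and Cd34, had a median change of -0.46 in Rag-deficient T-ALL (154 tested, 8 fell and none rose; camera adjusted p = 0.0422 with an estimated correlation). The sets of TN2 (median -0.12, adjusted p = 0.596 with an estimated correlation), TN3a (-0.13, 0.116), TN4 (-0.24, 0.116) and DP (-0.09, 0.596) were not called, and TN3b and ISP had no such genes. The ETP set also holds genes of myeloid cells such as Csf1r and Mpo, and the immunoglobulin genes Igk-C and Igkv1-110. The means of the myeloid and erythroid lists fell as well (-0.39 and -0.57). The shift of the set need not mean a different place along the developmental path. How many sets other splits of the arrays call is given in the closing part. With the slide as a fixed block 3 sets were called with the preset correlation. Leaving out Rag-proficient replicate 2 or Rag-deficient replicate 2 gave 3 called sets, and leaving out Rag-proficient replicate 4 or Rag-proficient replicate 6 gave 2.

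Set against the mean of the 7 stages, the most prominent genes of both T-ALL groups were those of red cells, myeloid cells and macrophages. In Rag-proficient T-ALL (n = 7) alpha globin (Hba-a1) was at least 928-fold higher, the red cell anion exchanger gene Slc4a1 at least 644-fold, and the haem synthesis gene Alas2 at least 226-fold. There the neutrophil calprotectin gene S100a8 was at least 223-fold and the adhesion gene Vcam1 at least 236-fold higher. In Rag-deficient T-ALL (n = 3) Hba-a1 was at least 852-fold, Slc4a1 at least 439-fold, Alas2 at least 147-fold and S100a8 at least 302-fold higher. Dtx1 was higher by 3.77 ± 0.20 (log2, SE) in Rag-proficient and 3.77 ± 0.27 in Rag-deficient T-ALL, and the oncogenes Lmo2 and Tal1 were at least 21.2-fold and 13.5-fold higher in the former and at least 10.6-fold and 7.17-fold in the latter. Among the largest falls were Dnajc6, a chaperone gene of clathrin uncoating (by -4.83 ± 0.17 and -5.99 ± 0.24), the homeobox gene Hoxa7 (at least 20.7-fold and 20.5-fold lower) and the histone demethylase gene Kdm5b (by -3.60 ± 0.22 and -4.39 ± 0.31).

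Limma called 6229 of 17417 genes in Rag-proficient T-ALL (3145 higher and 3084 lower) and 3220 in Rag-deficient T-ALL (1844 higher and 1376 lower), with adjusted p = 1.80e-13 for Dtx1 in the former. Of 10 erythroid markers all 10 rose in both groups, with a mean shift of 5.81 and 5.23. Myeloid and dendritic markers rose in 19 of 22 cases and fell in 1 (Siglech, by -2.40 ± 0.46) in Rag-proficient T-ALL, and rose in 16 and fell in 1 in Rag-deficient T-ALL. Thymic stroma markers rose in 9 of 18 cases and fell in 1 in Rag-proficient T-ALL, with Sparc at least 24.3-fold higher and Cxcl12 higher by 3.69 ± 0.28. In Rag-deficient T-ALL 4 of 18 stroma markers rose and 1 fell, with a mean shift of 0.33, and the list was not called (adjusted p = 0.388 with the preset and 0.727 with an estimated correlation).

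Beside those markers, Notch targets rose in 11 of 18 cases and fell in 1 (Hes5, by -0.94) in Rag-proficient T-ALL, with Notch3 up by 2.38 ± 0.20, and rose in 10 with none falling in Rag-deficient T-ALL. T-lineage genes rose in 12 of 20 cases and fell in 3, led by Cd2 (at least 14.0-fold) and the kinase gene Fyn (2.18) on one side and Dntt, terminal transferase (by -2.35 ± 0.26), on the other. In Rag-deficient T-ALL 11 rose and 2 fell. The mean of the stages includes ETP and TN2, where T-lineage genes can still be low. Cd3e was at 5.84 in ETP, 11.15 in TN2 and 12.35 to 13.58 in the later stages, against 12.72 in Rag-proficient T-ALL. Of the 20 T-lineage genes only 1 was above every stage in Rag-proficient T-ALL, and 1 was below every stage. Proliferation genes rose in 15 of 27 cases and fell in 2 in Rag-proficient T-ALL. There Cdk1 was up by 1.67 ± 0.16 (another Cdk1 probe was called lower) and Ccna2 down by -1.18. In Rag-deficient T-ALL 12 rose and 1 fell. The mean of the stages also includes TN3a and DP, where proliferation genes were lower than in TN3b and ISP. Of the 27 proliferation genes, 0 were above every stage in Rag-proficient T-ALL. With an estimated correlation, camera called erythroid (adjusted p = 0.00186), myeloid (0.00456), stroma (0.0464), T-lineage (0.0464) and Notch (0.0464) lists in Rag-proficient T-ALL. It did not call proliferation (0.0602), progenitor genes (9 rose and 3 fell of 22, 0.270), beta-selection (7 rose and 2 fell of 19, 0.482) or the BCL2 family (7 rose and 2 fell of 15, 0.0798). In Rag-deficient T-ALL it called erythroid (0.000649), myeloid (0.00757), Notch (0.0222) and T-lineage (0.0427) lists and not proliferation (0.0547). Adjusted over the list alone, 10 erythroid, 19 myeloid, 9 stroma, 12 T-lineage, 11 Notch and 15 proliferation genes rose in Rag-proficient T-ALL, and 10 erythroid, 17 myeloid, 11 Notch, 11 T-lineage and 13 proliferation genes in Rag-deficient T-ALL. In the same order 0, 2, 1, 3, 3 and 2 fell in Rag-proficient T-ALL, and 0, 1, 0, 2 and 1 in Rag-deficient T-ALL.

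T-ALL and thymocytes lay on different slides, so that slide lot and cell kind cannot be told apart here. Strain differed as well for Rag-proficient T-ALL, which came from a cross, but not for Rag-deficient T-ALL per the labels. In Rag-proficient T-ALL, 203 other probes of the called genes were called the opposite way. The authors' log2 table by probe ID, whose thymocyte columns did not match their signals, gave 14141 genes (9736 higher and 4405 lower) for Rag-proficient and 13095 (9048 and 4047) for Rag-deficient T-ALL. The Rag-deficient count was 2021 and 2049 without Rag-deficient replicates 1 and 2.

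A stricter comparison took genes at least 2-fold higher in Rag-proficient T-ALL than at each of the 7 stages. Strain and slide lot differ along with cell kind in this comparison too. There were 374 such genes, of which 300 were also called higher in Rag-deficient T-ALL against the mean of the stages and 45 were above background on no thymocyte array. They included all 10 erythroid markers, 9 of 22 myeloid, 4 of 18 stroma and 3 of 18 antigen presentation genes, beside 2 of 18 Notch targets, and 23 of the 31 that belonged to any list were erythroid, myeloid or stroma markers. Below every stage were 67 genes, of which 58 were also called lower in Rag-deficient T-ALL, and this count was 38, 41 and 26 without ISP replicate 1, DP replicate 1 and TN3b replicate 1. The genes above and below every stage came to 210 and 22 without background correction, 218 and 27 with the authors' log2 values matched by position, and 160 and 26 with array weights. Lmo2 and Tal1 were not among the genes above every stage. The ETP level of Lmo2 was 11.43 against 10.22 ± 0.33 (SD, n = 7) in Rag-proficient and 9.22 ± 0.78 (SD, n = 3) in Rag-deficient T-ALL. Against ETP, Tal1 differed by 1.10 ± 0.47 in Rag-proficient T-ALL (log2, SE, adjusted p = 0.0911).

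The similarity of each T-ALL array to each stage was computed over the 3683 genes that differed between stages, which asks where in thymic development T-ALL would stand. Rag-proficient T-ALL had its highest mean r with TN4 (0.227 ± 0.0346, SD, n = 7), then ISP (0.173 ± 0.0642), TN3b (0.105 ± 0.0494) and DP (0.0400 ± 0.0927). It had negative values with ETP (-0.0579 ± 0.0589), TN2 (-0.164 ± 0.0605) and TN3a (-0.226 ± 0.0260). Rag-deficient T-ALL had 0.292 ± 0.0586 with TN4 (SD, n = 3), 0.281 ± 0.0489 with ISP, 0.185 ± 0.101 with TN3b, 0.0357 ± 0.123 with DP and -0.151 ± 0.0417 with ETP. TN4 was the nearest stage of 7 arrays (5 Rag-proficient and 2 Rag-deficient) and ISP of the other 3. These r values are across genes, which are not independent replicates, and all were low.

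The r to DP minus the r to TN3a was 0.266 ± 0.102 (SD, n = 7) in Rag-proficient and 0.284 ± 0.0857 (SD, n = 3) in Rag-deficient T-ALL, a difference of 0.0177 (exact two-sided permutation test, p = 0.8). The difference became -0.00681 without Rag-proficient replicate 4 and -0.0291 without Rag-deficient replicate 2. Of the 7 stages, ISP gave the lowest p for r itself, a difference of 0.108 with p = 0.05 and an adjusted p of 0.136 over the 7 (exact permutation test). TN4 was the nearest stage of 4 arrays without TN4 replicate 3 and of 1 array when T-ALL values were centred on the T-ALL mean, where the mean r to TN4 was -0.0352 and 0.0752, so that the order of stages rests on the centring.

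**Figure D4:**
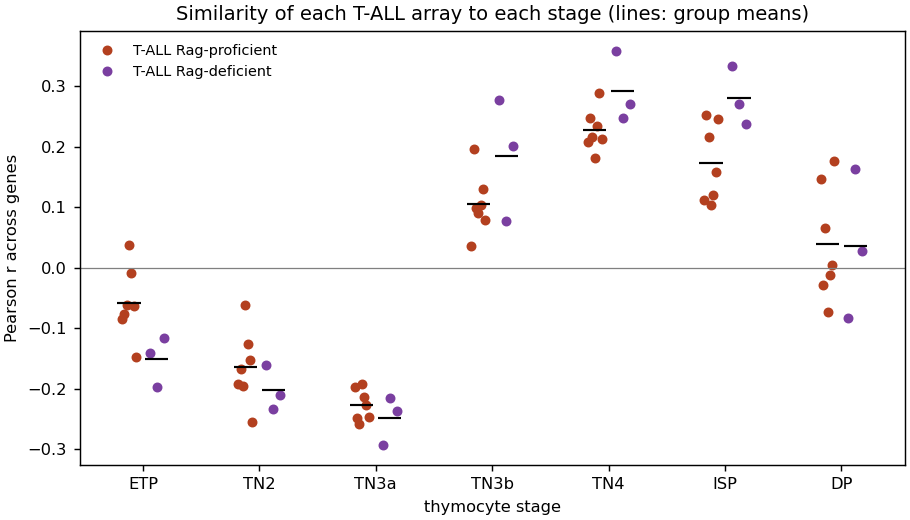
The y axis is Pearson's r across 3683 genes between a T-ALL array and a stage mean (x axis), both centred on the mean of the 7 stages, with points for arrays and lines for the means of Rag-proficient (n = 7) and Rag-deficient (n = 3) T-ALL. Both groups have their highest means at TN4 (0.227 and 0.292) and their lowest at TN3a (-0.226 and -0.248).

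Over all genes the median SD of each T-ALL group lay within the range of the stages. At the same spread, the median SD of 2 or 3 arrays tends to be lower than that of 7. Values of groups of unlike size thus cannot be compared directly. Arrays of a stage also lay on different slides, while the 3 Rag-deficient arrays shared a slide. The median SD over genes (log2) was 0.275 in Rag-proficient and 0.258 in Rag-deficient T-ALL, against 0.200 in ETP, 0.399 in TN2, 0.273 in TN3a, 0.181 in TN3b, 0.263 in TN4, 0.208 in ISP and 0.242 in DP. The genes that varied most among Rag-proficient arrays were immunoglobulin genes such as Igl-V1 (SD 4.62, from 4.16 to 14.45), pancreatic enzyme genes such as Amy2a5 (SD 4.26, from 4.18 to 14.20), and Cd163l1, a scavenger receptor gene of gamma delta T cells (SD 3.33, from 5.64 to 13.49). Il2ra ranged from 4.51 to 9.38 among the 7 Rag-proficient arrays and averaged 9.16 ± 0.32 (SD, n = 3) in Rag-deficient T-ALL.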

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

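Among the tests of this part, the one of slide lots for Tal1 and Lmo2 and the one of the antigen receptor loci were chosen after the results were seen.

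In the 7 Rag-proficient arrays, 9 of the 97 values tested had an array far from the others, where chance gives about 1 in 20, and all 9 were gene levels. Aldh5a1 was at 6.17 (log2) in replicate 4 against 4.16 to 4.53 in the others, and Erg, an ETS transcription factor gene, at 4.69 in replicate 5 against 4.17 to 4.37. Erg was above background on only 1 of the 7 arrays, so its levels lay near background. Replicate 6 stood apart in Bahcc1 (4.95 against 4.16 to 4.48), Hes5 (5.64 against 4.18 to 4.75), Lmo1 (4.40 against 4.10 to 4.16) and Tlx3 (4.62 against 4.11 to 4.32), the last 2 of these genes at levels near background. Replicate 7, the Rag-proficient array on the slide of the Rag-deficient ones, stood apart in Rag1 (11.48 against 8.86 to 9.97), Serping1 (5.92 against 8.12 to 9.22) and Siglech (5.00 against 4.11 to 4.42).

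When both T-ALL groups were set against the same stages in a fit of all arrays, the effects of 146 genes differed between them by a test of the difference (23 higher and 123 lower in Rag-deficient T-ALL). The stages cancel in that difference, so it is the comparison of the T-ALL groups with all arrays in one model given above, not a separate result. Of 148 probes that only the thymocyte table holds, 114 were above background on at least 2 arrays. Among 5924 tested probes with no gene name, 602 differed between the stages. No comparison of the report used these probes.

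Other splits of the arrays show how far chance goes, with 100 splits drawn for each result. For the 69 genes that differed between the T-ALL groups, 2 of the 100 splits gave as many, the real one included. Such a count was thus uncommon, but chance is not excluded, since the highest other split gave 154. What sets that split apart was not tested. That split put Rag-proficient replicate 4 with Rag-deficient replicates 1 and 2. With the slide as a fixed block the real split gave 24. The 7 gene lists called between the T-ALL groups were likewise an uncommon count (2 of 100 splits). Chance is not excluded for them either, as another split also gave 7 and the median of the other splits was 3. These splits take no account of the slide, and 3 of the 7 lists kept their call with the slide as a fixed block and 0 with an estimated correlation. The 1 stage set called with the preset correlation was a common count (75 of 100 splits, highest other 4), so that chance cannot be excluded for it.

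Against the stages, the 6229 genes of Rag-proficient T-ALL were matched by no other draw of the labels (1 of 100, highest other 83). The same held for the 3220 of Rag-deficient T-ALL (1 of 100, highest other 140). It also held for the 374 genes above every stage and the 67 below (1 of 100 each, highest other 0). Other draws mix T-ALL and thymocyte arrays, and thus slide lots, within a group, which by itself lowers their counts. A random draw of arrays into groups is thus excluded as the source. The draws cannot part cell kind from slide lot, or from strain in Rag-proficient T-ALL. For the number of gene lists called with the preset correlation chance cannot be excluded: 9 were called in Rag-proficient T-ALL (10 of 100 draws gave as many, highest other 15) and 5 in Rag-deficient T-ALL (66 of 100, highest other 12). That count does not speak of any list by itself.

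Tal1 and Lmo2 were higher in T-ALL than at most thymocyte stages, and both are also genes of red cell precursors. Their mean followed the erythroid marker mean over the 10 T-ALL arrays (Pearson's r = 0.955 across arrays, permutation p = 3e-05, adjusted p = 9e-05 over 3 relations), and r was 0.897 without the 2 farthest arrays and 0.956 within the 7 Rag-proficient ones (exact p = 0.00159). RNA of erythroid cells in the T-ALL preparations may thus account for them, whereas r with the myeloid marker mean was 0.191 (permutation test, p = 0.609) and with the stroma marker mean 0.572 (p = 0.0819). The bound set beforehand did not settle RNA of ETP stage cells. In Rag-proficient T-ALL the ETP set lay at a median of -1.89 against ETP (upper quartile -1.07), with Lmo2 at -1.21 and Tal1 at 1.10. Such RNA would bring all ETP genes along at the same share, but the lower quartile of the set was -2.90. Kit was at 12.37 in ETP and at most 9.01 on the 7 Rag-proficient arrays. These values argue against ETP RNA as the source of Lmo2 and Tal1 in Rag-proficient T-ALL. A difference between slide lots stays open, because cell kind and slide lot differ together (71.5% of the other probes of called genes had the called direction). So does an oncogenic role in the T-ALL cells, which was not tested.

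Genes lower in Rag-deficient T-ALL included stromal ones, and more stromal RNA in the Rag-proficient preparations is a candidate explanation: the median r with the stroma list over the 7 Rag-proficient arrays was 0.527 for 61 genes outside that list, while 1000 random sets reached at most 0.281. A difference between slides cannot be told apart. The 79 genes called without the Rag-proficient array of slide 3 had a median change of 1.82 against it, all 79 in the called direction (median 2.28 in the other arrays). This met the bound set beforehand, but it is 1 array set against the Rag-deficient arrays behind the calls. With the slide as a fixed block Serping1 went from -4.44 to -1.99, Tcrg from -4.95 to -2.72 and the stroma list from -0.83 to -0.34 (camera adjusted p = 0.658). Igk-C (-7.62 to -7.09), Tcrg-V4 (-4.78 to -4.25) and Trdv2-2 (2.38 to 2.33) changed less, though none of these genes kept its call. Strain background stays open, as Rag status and strain differ together and 75.4% of the called genes lay nearer to the stages in Rag-deficient T-ALL. Loss of rearranged antigen receptor loci stays open as well. Over 37 such genes the median change was -0.58, and 26 had a negative change (3 called lower, 1 higher, camera p = 0.217 with an estimated correlation). Most immunoglobulin genes were lower, of which only Igk-C was called, while T cell receptor genes went both ways.

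Pancreatic enzyme genes were high in 4 T-ALL arrays, namely Rag-proficient replicates 5 and 7 and Rag-deficient replicates 1 and 2. RNA of pancreas in these preparations is a candidate explanation: 19 further pancreatic genes, not looked at before, followed the 6 seen ones with a median r of 0.957 over the 10 arrays, while random sets reached at most 0.410. A difference between slides is argued against, since 2 of the 3 slides held arrays both above and below the midpoint. No biological explanation was tested.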

How the results depend on the processing

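The authors' log2 table with thymocyte columns matched by position, and every alternative for the stage sets and for the spread between arrays, were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers or animals, and the numbers used here follow the order of deposition. Arrays that share a slide were compared with the slide as a block and within slides. The cause of the changes below was not tested, except where the alternative itself shows it.

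Without background correction, 6 genes were called from TN3b to TN4, 14 from TN4 to ISP and 42 between the T-ALL groups, with 2 stage sets, 210 genes above and 22 below every stage. The spread between arrays was then 0.128 in Rag-proficient and 0.119 in Rag-deficient T-ALL, and r to TN4 was 0.282 and 0.351. The authors' log2 table by probe ID gave 204, 284, 301, 8, 7 and 996 genes over the 6 steps in order, 1779 between the stages, 27 between the T-ALL groups and 2 stage sets. Against the stages it gave 14141 genes in Rag-proficient and 13095 in Rag-deficient T-ALL, 4946 above and 1856 below every stage, because its thymocyte columns did not match their probes. The spread was 0.135 and 0.125, r to TN4 was -0.123 in both groups, 0 arrays were nearest to TN4, and the difference in r to DP minus r to TN3a was 0.00434 (exact permutation test, p = 0.025). Matched by position, the table gave 18 genes from TN4 to ISP, 218 above and 27 below every stage, the same spread (0.135 and 0.125), and an r to TN4 of 0.277 in Rag-proficient T-ALL.

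With no filter on detection 3 stage sets were called, and with detection on all arrays of a group 23 genes from TN3b to TN4. A 2-fold minimum left 1909 genes in Rag-proficient and 1577 in Rag-deficient T-ALL against the stages, by its construction. Array weights gave 106, 92, 2008, 208 and 144 genes over the first 5 steps, and 160 above and 26 below every stage. The slide as a random block gave 661, 1086, 1279 and 32 genes over the first 4 steps and 108 between the T-ALL groups. The slide as a fixed block gave 987 from TN2 to TN3a, 1451 from TN3a to TN3b, 24 between the T-ALL groups and 3 stage sets. All 26 arrays in one model gave 605, 1188 and 31 genes for ETP to TN2, TN2 to TN3a and TN3b to TN4, and 146 between the T-ALL groups.

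The r to TN4 was 0.189 in Rag-proficient and 0.227 in Rag-deficient T-ALL over all detected genes and 0.311 and 0.370 with Spearman's rho. Centred on the T-ALL mean it was -0.0352 and 0.0752, with 1 array nearest to TN4. With Spearman's rho the difference in r to DP minus r to TN3a was -0.0326 (exact permutation test, p = 0.675). With an estimated correlation 33 of the 82 list calls remained past the threshold (21 up and 12 down).

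Leaving out each array in turn gave 189 to 3711 genes from ETP to TN2, 348 to 4167 from TN2 to TN3a, 220 to 1296 from TN3a to TN3b, 2 to 121 from TN3b to TN4, 6 to 151 from TN4 to ISP and 1199 to 2729 from ISP to DP. It gave 2947 to 6802 between the stages, 35 to 115 between the T-ALL groups and 1 to 3 stage sets. Against the stages the counts were 5568 to 7422 in Rag-proficient and 2021 to 4382 in Rag-deficient T-ALL, with 278 to 402 genes above and 26 to 73 below every stage. The spread was 0.263 to 0.280 and 0.192 to 0.260, r to TN4 0.189 to 0.284 and 0.259 to 0.325, and 4 to 10 arrays were nearest to TN4. The difference in r to DP minus r to TN3a ran from -0.0291 to 0.0549, with -0.00681 without Rag-proficient replicate 4 and -0.0291 without Rag-deficient replicate 2. Where a stage was left with 1 array, limma pooled the spread, so that the lone array is assumed to vary like the others.

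No named gene reversed in the settings counted next, which keep 1 probe per gene. Another probe of the gene was called the opposite way for Cdk1, Ptprc, Cd44 and Prf1 in Rag-proficient and for Cdk1, H2-K1 and Prf1 in Rag-deficient T-ALL against the stages. Calls were lost for 10 of 209 named genes without background correction, 6 with no filter, 2 with a 2-fold minimum, 11 with array weights, and 0 with the slide as a random block or detection by group. They were lost for 17 of 145 with the slide as a fixed block and 14 of 145 with all arrays in one model. In the authors' log2 values 5 of 12 were lost between the T-ALL groups, and 5 of 197 when matched by position. Of the 82 list calls 18 were lost with fry, and 2 of 75 without the proliferation genes. Signal over background limits the dim genes: a probe below background bounds its fold, and TN2 replicate 2, with 28.5% of probes detected, limits the TN2 steps.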

Other observations

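The list of cell type markers in this part was chosen after seeing which genes lay above every stage, so the counts below are not a test. Some of the neutrophil genes, Camp among them, also belong to the myeloid list. Genes typical of spleen red pulp macrophages were higher in both T-ALL groups than in the mean of the stages, 8 of 8 in each. Slc40a1, the iron exporter gene, was at least 150-fold higher in Rag-proficient (n = 7) and at least 71.2-fold in Rag-deficient T-ALL (n = 3), Fcna, a ficolin gene, at least 123-fold and 46.8-fold, and Spic, a transcription factor of these macrophages, at least 31.7-fold and 14.5-fold. Neutrophil granule genes rose in 6 of 6 cases in each group, such as Lcn2 (at least 25.4-fold and 30.6-fold) and Camp (at least 17.4-fold and 33.2-fold). Platelet genes rose in 4 of 4, such as Pf4 (at least 25.3-fold and 9.88-fold), and eosinophil genes in 2 of 3, with Epx not called (0.09 ± 0.09, log2, SE, adjusted p = 0.441). The labels do not name the tissue of the T-ALL samples.

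Sex-linked genes differed between slides. Xist, expressed from the inactive X chromosome, was at 7.47 to 10.72 (log2) on the 6 thymocyte arrays of slides 4 and 5, and at 4.10 to 4.49 on the 10 of slides 6 and 7. Eif2s3y, a gene of the Y chromosome, was at 8.49 to 9.74 on the arrays of slides 6 and 7. On slide 4, TN3a replicate 1 and TN4 replicate 1 had both Xist (8.75 and 7.73) and Eif2s3y (7.77 and 7.94), and the other arrays of slides 4 and 5 had Eif2s3y of at most 4.31. In T-ALL, Rag-proficient replicate 7 had the highest Xist (10.02) with Eif2s3y at 6.34, and the Rag-deficient arrays had Eif2s3y of 7.07, 9.04 and 8.25. Rag-proficient replicate 1 (Xist 6.36, Eif2s3y 8.56) and Rag-deficient replicate 3 (5.90 and 8.25) had both, so these genes do not part the T-ALL groups.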
